A study of Mus musculus with 2 samples.

How the data were processed

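Gene expression was measured in single cells of the mouse pancreas at embryonic day 14.5 with the 10x Genomics droplet assay, which tags each captured RNA molecule near its 3' end with a cell barcode and a unique molecular identifier (UMI). The Control library pooled 8 pancreata from 3 litters with genotypes Fgf9 +/+ and +/-, and the Null library pooled 3 pancreata from 3 litters in which a LacZ cassette disrupted both copies of Fgf9. Mice were on a C57BL/6J background. Per the labels' protocols, tissue was dissociated with TrypLE, live cells were sorted as DAPI-negative after a size gate against doublets, and libraries were sequenced on an Illumina NovaSeq. Per the submitters' processing notes, bcl2fastq, Cell Ranger 6.1.1 and Seurat 3.2.3 were used with the mm10 build. The deposited values are whole-number UMI counts per gene and barcode, not normalized, which the authors produced with Cell Ranger per the file headers. No cell annotation was used here, and whether counting used strand is not given in the sources used here.

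Of the 32285 features, 32158 (99.6%) had their gene identifier in the GENCODE vM21 annotation of GRCm38, from which coordinates were taken. The 31 gene lists, the cell type markers, the cell filter and the alternatives were fixed before the data were examined, and 3 of the symbols on the lists matched no feature. Barcodes were kept with at least 1000 UMIs, at least 300 detected genes and under 15% mitochondrially encoded UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5. Its automatic threshold of 0.548 marked 0% of the Control barcodes, so the score of 0.25 set in advance for that case was used and marked 209 of 27179 barcodes (0.769%). In the Null library the automatic threshold marked 584 of 9404 barcodes (6.21%). Called doublets were removed, and the low Control share means that more doublets may remain in that library. On barcodes of at least 5000 UMIs the automatic threshold of the same caller marked 1270 of 13619 Control barcodes (9.33%) and 319 of 7608 Null barcodes (4.19%).

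Both libraries were clustered together without batch integration. Counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used, with sex-linked, haemoglobin, mitochondrially encoded, ribosomal protein and immediate early genes left out of the variable genes. A cluster took the class whose fixed markers stood highest above the 25th percentile of clusters, with at least 3 markers above 1 on the log2 scale in at least 10% of its cells. These naming thresholds were set after the data were seen. They left unnamed a cluster of low UMI counts with 10837 Control barcodes (40.2% of those kept) and 310 Null barcodes (3.51%), and a cluster with mesenchymal and acinar markers at high UMI counts with 209 Control barcodes (0.775%) and 10 Null barcodes (0.113%). Epithelial cells were clustered again for their subclasses, and epithelial clusters without a subclass held 880 Control cells (8.83% of epithelial cells) and 249 Null cells (4.18%). Classes are marker-based and are called mesenchymal-like, acinar-like and so on, shortened to the class name after first use.

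With 1 library per group there was no test between groups, and no p-value or count of changed genes is given. UMIs were summed per library and class and expressed as CPM (UMIs scaled to a common class total), over the class total without haemoglobin and mitochondrially encoded genes. The log2 ratio of Null over Control CPM carries the exact conditional 95% interval for a pair of Poisson counts, and shares of cells carry exact Clopper-Pearson 95% intervals. Intervals of list medians come from 200 Poisson redraws of the counts. All intervals cover counting error only, not differences between embryos or between library preparations. A count of 0 was set to a floor of 3 counts per library for ratios, and the share that 0 cells allow is given as 3 of the cells. Classes with at least 200 kept cells in each library were compared. A list median covers members with at least 20 UMIs in the class over both libraries. It is set beside 10000 random lists of the same size matched on mean CPM in 20 bins, as a description of these libraries. Shares of cells with a UMI were compared after each cell was thinned to 2000 UMIs, with shallower cells left out.

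Named genes had at least 100 UMIs in the class, at least 20 CPM in the higher library, a class CPM of at least 50% of the CPM over all kept cells of that library, and an interval excluding 0. They were ranked by the interval bound nearest 0. The first 10 in each direction were taken for mesenchymal cells, 8 for acinar and ductal cells, 5 for mesothelial cells and 3 for other classes, and the rule also allows members of the fixed lists. Predicted gene models need not be named. Of the lists, those whose results bear on the comparisons are described in the text.

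The interval and list code was tested on simulated Poisson counts with 100 genes altered by 1 and 100 by 2 on the log2 scale. In the mesenchymal comparison, over 11704 genes, 98.0% of the genes altered by 1 and 100.0% of those altered by 2 had an interval on the correct side of 0, and 95.4% of the unaltered genes had an interval holding 0. In the mesothelial comparison, over 11342 genes, these shares were 99.0%, 100.0% and 95.6%.

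Alternatives fixed in advance covered the cell filter, doublets, clustering resolution, principal components, genes used for clustering, library scaling (TMM factors from edgeR 4.0.16 in R 4.3.3, median of ratios, CPM over all genes), weighting of cells and clusters, thinning and the minimum count. Added after the data were seen were the named-class denominator, a stricter set of barcodes with at least 5000 UMIs and under 10% mitochondrially encoded UMIs, with doublets called and cells clustered again, the removal of the barcodes of that second doublet call from the classes, a comparison of cells with Y-linked UMIs in both libraries, and a subtraction of free RNA. Free RNA was estimated per library from the unnamed low-UMI barcodes and scaled on the acinar enzyme UMIs of each class. That these barcodes hold only free RNA was not tested, so every free RNA share below is an estimate under that assumption. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and leidenalg 0.10.2, and plots were drawn with matplotlib 3.10.9.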

Results

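The series asks what loss of Fgf9, a secreted fibroblast growth factor, does to the developing mouse pancreas. It holds 1 Control library of 30209 barcodes with 339959625 UMIs and 1 Null library of 16708 barcodes with 271129120 UMIs. After filtering, 26970 Control barcodes (median 5751.5 UMIs) and 8820 Null barcodes (median 24267.5 UMIs) were kept. Of these, 15924 Control barcodes (median 15271 UMIs) and 8500 Null barcodes (median 24942 UMIs) fell in a named class. Because each group is 1 pooled library, no difference below has a replicate check, and every interval covers counting error only.

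The libraries also differed in the sex of their cells. Xist, the RNA that silences an X chromosome in female cells, stood at 384 CPM in the Control library and 0.288 CPM in the Null library. Among cells that could be called, 52.1% of Control cells and 99.986% of Null cells carried Y-linked UMIs with at most 1 Xist UMI. Tsix, transcribed antisense to Xist (GRCm38 chromosome X, 103431517 to 103484957), was among the genes lower in the Null library in each class compared, and its reads cannot be told apart from those of Xist if strand was not used.

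Fgf9 (ENSMUSG00000021974, GRCm38 chromosome 14, 58070547 to 58112720, plus strand) was lower in the Null library. Over all kept cells it had 2901 UMIs in the Control library, 9.28 CPM (8.95 to 9.63), and 410 UMIs in the Null library, 1.71 CPM (1.55 to 1.89), a log2 ratio of -2.44 (-2.59 to -2.29). Mesothelial-like cells, the covering layer of the organ, held most of these UMIs, with 1987 UMIs and 96.1 CPM (92.0 to 100.5) in the Control library and 372 UMIs and 37.7 CPM (34.0 to 41.8) in the Null library. Ductal or bipotent progenitor-like cells had 4.12 CPM in the Control library and 0.114 CPM in the Null library, and endocrine-like cells 7.66 and 0.113 CPM. Unnamed barcodes, mostly of low UMI counts, had 3.18 (2.53 to 3.94) and 1.08 (0.0273 to 6.01) CPM, so free RNA adds to these epithelial values. The labels do not say which part of the gene the LacZ cassette disrupts, and the 3' tag may lie outside it, so the UMIs that remain in the Null library check nothing about the allele.

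The question of tissue makeup was addressed by the share of cells per class. Among cells of a named class, mesenchymal-like cells made up 20.2% (19.6 to 20.8) of the Control library and 12.6% (11.9 to 13.3) of the Null library, a ratio of 0.624 (0.585 to 0.665). Epithelial-like cells made up 62.6% (61.8 to 63.3) and 70.1% (69.1 to 71.1). Within the epithelium, acinar-like cells, which make digestive enzymes, were 32.6% (31.6 to 33.5) of Control and 41.4% (40.1 to 42.7) of Null epithelial cells. Endocrine progenitor-like cells were 10.7% (10.1 to 11.3) and 7.55% (6.89 to 8.25), ductal or bipotent progenitor-like cells 33.7% and 31.9% (32.0% and 22.9% with 50 principal components), and endocrine-like cells 14.2% and 15.0%. The planned denominator, all kept cells, holds the 10837 unnamed low-UMI barcodes of the Control library. Over it the mesenchymal shares were 11.9% and 12.1%, the epithelial shares 36.9% and 67.6%, and the mesothelial shares 6.61% and 9.35%. Over named cells, a denominator chosen after the data were seen, the mesothelial order turned, with 11.2% in the Control and 9.71% in the Null library. Live-cell sorting with a size gate and the UMI minimum can set all of these shares.

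**Figure D1:**
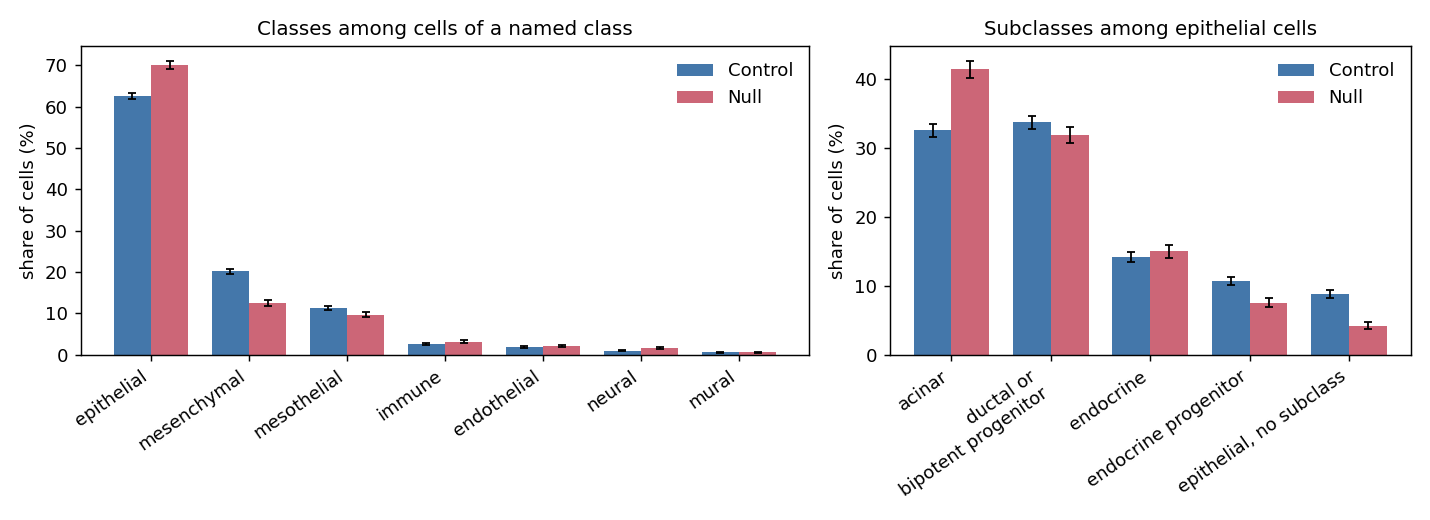
Share of cells (%) per class among cells of a named class (left) and per subclass among epithelial cells (right), for the Control and Null libraries. Bars start at 0 and lines are exact Clopper-Pearson 95% intervals (counting error only); mesenchymal cells are 20.2% of Control and 12.6% of Null named cells.

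In mesenchymal-like cells, the connective tissue around the epithelium, the fixed list of spleen and stomach mesenchyme transcription factors went both ways, with 9 of 15 measured members higher in the Null library and a median of 0.18. Foxf1 at 2.51 and Nr2f1 at 2.04 led its higher members, and 4 members, named here because they were low, stood out in the other direction. Tlx1, needed for spleen formation (GRCm38 chromosome 19, 45150680 to 45156943), had 31.4 CPM in the Control library and 0.958 CPM in the Null library, a log2 ratio of -5.03 (-5.95 to -4.25). Nkx2-5 stood at -3.15, Nkx3-2 at -2.24 and Barx1, a stomach mesenchyme factor, at -2.01 (-2.15 to -1.87), from 140 to 34.7 CPM. With each cell thinned to 2000 UMIs, Tlx1 was detected in 5.66% (4.85 to 6.56) of Control and 0.124% (0.0031 to 0.688) of Null mesenchymal cells. The unthinned shares were 16.8% and 1.03%, at median depths of 7868 and 13410 UMIs. Acinar cells, which should lack Tlx1, had 0.0309% thinned and 0.462% unthinned in the Control library (median 31732 UMIs) and 0 of 2467 unthinned in the Null library (median 47717 UMIs), which allows up to 0.122%.

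Genes of the extracellular matrix were higher in Null mesenchymal cells. Of 24 fibrillar collagen and matrix genes, 23 were higher, with a median log2 ratio of 0.66 (0.64 to 0.69) that lay above all 10000 random lists. It was 0.37 with clusters weighted alike and 0.40 once free RNA was subtracted. Tnc, the matrix glycoprotein tenascin C, stood at 3.41, Fn1, fibronectin, at 2.15 and Lum at 1.43, while Fbln5 stood at -0.58. Basement membrane genes had a median of 0.51 (0.28 at the lowest of its alternatives), with 14 of 16 higher, led by Col4a6 at 3.19 and Lama2 at 2.43. TGF-beta target genes had a median of 0.75, with 11 of 12 higher. Smooth muscle genes had a median of 0.80, with 11 of 12 higher, but this median lay as low as 0.12 under another cell set. A cluster of 3 Control and 111 Null cells within the class, with Tagln among its leading genes, matched the mural markers best. Their member Actg2 stood at 2.77, and at -0.68 in barcodes of at least 5000 UMIs. The dissociation and immediate early genes were also higher in the Null library, with a median of 0.48 and 22 of 24 members higher.

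FGF/ERK feedback and target genes, which report receptor signaling, showed no common direction in mesenchymal cells. Their median was 0.10 (-0.07 to 0.17), with 9 of 14 higher, from Spry1 at -0.81 to Spry2 at 0.79 and Dusp6 at 0.51. Of the FGF receptors and co-receptors, Fgfr4 stood at -2.06, Fgfr2 at -0.36 and Fgfr1 at 0.08. Wnt/beta-catenin target genes had a median of -0.37, with 8 of 10 lower and Notum at -2.28, and this median was 0.12 when clusters were weighted alike. Retinoic acid pathway genes had a median of -0.38, which ran from -1.13 to -0.22 over its alternatives, with Aldh1a2 at -3.13 and Cyp26b1 at -3.10. Aldh1a2 is also a fixed mesothelial marker, so mesothelial cells or RNA within the Control mesenchymal class are not excluded as a source of its value. G2/M genes had a median of 0.30, with 28 of 30 higher, and of -0.07 with clusters weighted alike. The share of cells with Mki67 or Top2a, genes of dividing cells, was 36.6% (34.9 to 38.4) in the Control and 35.02% (31.7 to 38.4) in the Null library after thinning, which left out 267 and 263 shallower cells, and 61.0% and 56.6% before. By the estimate, free RNA carries these transcripts and made up more of the UMIs in the Control library. Endocrine cells, where free RNA accounts for most G2/M UMIs under that estimate, had 17.0% and 5.70% after thinning (median depths 12718 and 20017 UMIs). The shares in this and the other classes therefore do not show which library held more dividing cells.

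Among the genes ranked highest in Null mesenchymal cells were Mab21l2 at 5.21, Trac at 4.94, Stmn2 at 3.07, Cttnbp2 at 3.10, Angpt1, a vessel growth factor, at 2.87, Palld at 2.78, Col15a1 at 2.82, Mgp at 2.55 and Actg2. With clusters weighted alike, Trac stood at 3.54, Cttnbp2 at 2.01, Palld at 1.99, Stmn2 at 1.66, Mgp at 1.25 and Actg2 at 0.99. Among the lowest besides Tsix and Tlx1 were Syt6 at -2.45, Slitrk5 at -2.36, Wnt5a, a secreted Wnt ligand, at -2.22, Rgcc at -2.10, Barx1, Lpar1 at -1.86 and Ntrk2 at -1.84. Cluster 2 held the most Control cells of the class (1736, with 251 Null cells), cluster 7, of low UMI counts, the most Null cells (348, with 989 Control cells), and cluster 21, led by Mgp, Dcn, Stmn2 and Lum, held 149 and 323. Of the lowest genes, Barx1 stood at -3.09 in all other kept cells, Syt6 at -2.50, Wnt5a at -1.38 and Ntrk2 at -1.23. Slitrk5 stood at -1.01, Lpar1 at -0.48 and Rgcc at 0.02 there. When mesenchymal cells were clustered again, some clusters were nearly of 1 library and others mixed. A cluster with Rgcc, Lpar1 and Barx1 among its leading genes held 813 Control and 2 Null cells, one led by Tlx1 and Syt6 held 618 and 15, and one led by Plac8 held 24 and 289, so these genes partly define the clusters. Clusters led by histone, S phase and G2/M genes mixed both libraries (228 and 118, 150 and 57, 143 and 63). Low-UMI clusters with acinar and endocrine genes among their leading genes held 721 and 55, 36 and 243, and 208 and 32 cells. In this second clustering the marker rule named those of 721 and 55 and of 36 and 243 cells acinar. They stayed in the mesenchymal class and count in its shares, ratios and medians. Markers of other cell types were lower in Null mesenchymal cells at the same time, with medians of -1.22 for acinar enzymes (15 of 15 lower) and -1.31 for mesothelial genes, though the mesothelial genes stood at 2.34 in barcodes of at least 5000 UMIs. The acinar enzymes place the free RNA share at 22.9% of UMIs in Control and 6.79% in Null mesenchymal cells.

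In mesothelial-like cells, the main site of Fgf9 UMIs, FGF/ERK feedback and target genes were lower in the Null library. Of 13 measured members 11 were lower, and the median of -1.21 (-1.36 to -0.89) lay below all 10000 random lists. Ccnd1, a cyclin that drives entry into S phase, went from 95.9 to 13.3 CPM, a log2 ratio of -2.85 (-3.12 to -2.60). The feedback inhibitors Il17rd and Spry4 stood at -1.82 (-2.28 to -1.39) and -1.74 (-3.71 to -0.22), the transcription factors Etv5 and Etv1 at -1.22 and -1.21, and Spred3 and Spred1 at 0.18 and 0.14. The median was -0.72 with clusters weighted alike and -0.70 as the mean over cells. A second doublet call, on barcodes of at least 5000 UMIs, marked 16.3% of the scored Control and 0.649% of the scored Null mesothelial cells. Without them the median was -0.72, Ccnd1 stood at -1.99, Il17rd at -2.10 and Fgfr4 at -2.40. Trunk and ductal genes went from -2.40 to -1.34, though Krt19 and Krt7 on that list are also fixed mesothelial markers. Acinar enzymes, foreign to this class, went from -1.57 to -0.76, so RNA of epithelial cells still differs between the libraries in this class. Among FGF ligands, Fgf16, in the same subfamily as Fgf9, stood at -2.36 and Fgf8 at -2.05, while Fgf1 stood at 1.76, Fgf10 at 1.52 and Fgf2 at 1.22. Fgfr4 was lower at -3.22 and Fgfr1 stood at -0.05.

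Matrix genes were higher in Null mesothelial cells too, with 23 of 24 higher and a median of 1.68 (1.62 to 1.78), above all 10000 random lists. Tnc had 4 UMIs in the Control library and 113 in the Null library, a log2 ratio of 5.89, and Lum stood at 3.14 and Postn at 2.85. Several matrix genes are also mesenchymal markers, and of 7 measured mesenchymal markers outside the matrix list 5 were higher in the same cells, from Prrx1 at -1.48 to Twist1 at 2.70, so a different mix of mesothelial and mesenchymal cells within the class is not excluded. TGF-beta target genes had a median of 1.39, with 12 of 13 higher. BMP targets and ligands had a median of 0.52, but of 0.08 with every cell thinned to 2000 UMIs, and Msx2 stood at 5.65. Notch pathway genes had a median of -0.64, with 12 of 15 lower, but of -0.18 as the mean over cells. Cholesterol synthesis genes had a median of -0.84, with 16 of 16 lower. S phase genes had a median of -0.52, with 25 of 25 lower, and of -0.23 with clusters weighted alike. G2/M genes had a median of -0.46, with 29 of 30 lower, but of 0.21 with clusters weighted alike. Cells with Mki67 or Top2a were 41.3% (38.9 to 43.8) of Control and 23.4% (19.9995 to 27.1) of Null mesothelial cells after thinning, which left out 167 and 248 shallower cells, and 67.0% and 42.8% before. Dissociation and immediate early genes had a median of 0.58.

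Ranked highest in Null mesothelial cells were Apela at 4.26, Pnoc at 3.72, Oprk1 at 3.53, Angpt1 at 3.74 and Sema3e at 3.79. The lowest besides Tsix were Crabp1, a retinoic acid binding protein, at -3.51, Ppp1r14c at -3.83, Sorcs3 at -3.25 and Vtn at -2.62, which moved to -1.38 as the mean over cells and to -1.60 without barcodes of the second doublet call. Barx1 stood at -2.19, and Msln, mesothelin, at 3.39. Cluster 18, led by Aldh1a2 and Barx1, held 427 Control and 65 Null cells, cluster 8 held 785 and 428, and cluster 11, of low UMI counts and with Crabp1 and Barx1 among its leading genes, held 571 and 332. Acinar enzymes had a median of -1.57 in this class, and they place the free RNA share at 33.0% of UMIs in Control and 7.88% in Null cells, and at 19.3% and 7.92% without barcodes of the second doublet call.

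**Figure D2:**
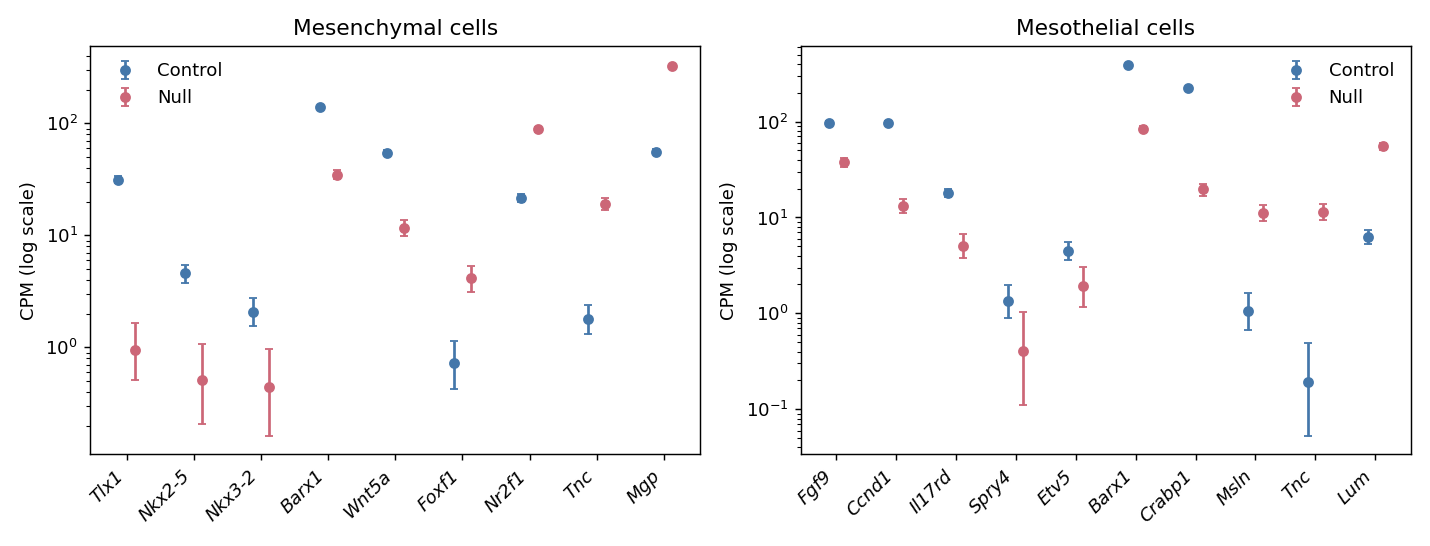
CPM (log scale) of genes named in the text in mesenchymal (left) and mesothelial cells (right) of the Control and Null libraries, chosen after their values were seen. Points are summed UMIs per class and lines exact Poisson 95% intervals (counting error only); Tlx1 lies at 31.4 CPM in Control and 0.958 CPM in Null mesenchymal cells.

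In acinar-like cells, digestive enzyme genes were higher in the Null library. Of 18 measured, 16 were higher, with a median of 0.63 (0.59 to 0.64), above all 10000 random lists, and of 0.40 with clusters weighted alike. Cuzd1 stood at 2.23, Cela2a, an elastase, at 2.04 and Cpb1, a carboxypeptidase, at 1.62, while Prss2 stood at -0.18. Unfolded protein response genes had a median of 0.23, with 14 of 14 higher. FGF/ERK genes had a median of -0.32 (-0.38 to -0.24), with 13 of 15 lower, led by Etv4 at -2.01, Ccnd1 at -0.90 and Etv5 at -0.88, and the median was -0.20 with clusters weighted alike. Cholesterol synthesis genes had a median of -0.37, with 16 of 16 lower, and G2/M genes one of -0.14. By rank, Serpina1c at 1.90, Try10 at 1.74, Prss1 at 1.72, Pdia2 at 1.73 and Serpina1b at 1.68 followed Cela2a, and Pttg1 at -1.11, Snhg9 at -1.08, Mxra7 at -1.01, Ccnd1, Cda at -0.85 and AA465934 at -0.87 were lowest besides Tsix. In all other kept cells, Pttg1 stood at -0.82, Snhg9 at -1.12, AA465934 at -0.96 and Serpina1c at 1.12, so these differences reach beyond acinar cells. Mxra7 stood at -0.07, Ccnd1 at -0.26 and Cda at -0.42 there. The trypsinogen genes Try10, Prss1 and Prss2 and the Serpina1 genes have near-identical copies, so their single values are uncertain. Cells with Mki67 or Top2a were 55.0% of Control and 52.3% of Null acinar cells after thinning (11 and 31 cells left out), and 94.5% and 91.8% before. When epithelial cells were clustered again, the acinar cluster with the most Control cells held 974 Control and 428 Null cells. The one with the most Null cells, led by Try5, Cela2a and Try10, held 319 and 690, so these genes partly define it.

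In ductal or bipotent progenitor-like cells, which line the epithelial trunk, FGF/ERK genes were lower and trunk genes slightly higher in the Null library. The FGF/ERK median was -0.32 (-0.43 to -0.15), with 12 of 15 lower, led by Etv1 at -1.22 and Etv5 at -1.08. This median was -0.19 at the highest of its alternatives. Trunk and ductal genes had a median of 0.22, with 11 of 14 higher, led by Cftr, a chloride channel, at 1.32. Basement membrane genes had a median of 0.33, with 13 of 15 higher. Ranked highest were Tgfb2 at 1.85, Cryab at 1.84, Cdh6 at 1.40, Hivep2 at 1.38, Ahnak at 1.36, Slc2a2, a glucose transporter, at 1.27, Shisa4 at 1.32 and Tagln at 1.25. Lowest besides Tsix were Pttg1 at -1.05, Snhg9 at -1.04, the BMP targets Id1 at -0.85 and Id3 at -0.80, Dlk1 at -0.79, AA465934 at -0.85 and Aldh1b1 at -0.65. In all other kept cells, Pttg1 stood at -0.90, Snhg9 at -1.08 and AA465934 at -0.93, so these were lower beyond this class. Id1 stood at -0.30, Dlk1 at -0.23, Aldh1b1 at -0.17 and Id3 at 0.08 there. TMM factors shift each ratio in ductal cells by -0.09. Acinar enzymes had a median of -0.86 here. Cells with Mki67 or Top2a were 48.2% of Control and 42.8% of Null cells after thinning (7 and 20 left out), and 82.8% and 75.6% before. The ductal cluster with the most Control cells, with Ccnd1 among its leading genes, held 1041 Control and 274 Null cells, and the one with the most Null cells, led by Dcdc2a and Cxcl12, held 991 and 900.

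In endocrine-like cells, hormone and secretory genes were higher and cell cycle genes lower in the Null library. Of 18 hormone and secretory genes 16 were higher, with a median of 0.49 (0.46 to 0.51), and of 0.32 once free RNA was subtracted. They were led by Sst, somatostatin, at 1.09 and the insulin genes Ins1 and Ins2 at 1.02 and 1.01. The clusters led by Ins1 and by Sst held 185 and 42 of 1415 Control and 196 and 35 of 894 Null endocrine cells. These hormone ratios therefore mix cell numbers with expression per cell. Unfolded protein response genes had a median of 0.32, and of 0.20 at the lowest of its alternatives. G2/M genes had a median of -1.63 (-1.70 to -1.49), with 30 of 30 lower, and S phase genes one of -0.75, with 25 of 25 lower. Once free RNA was subtracted the S phase median was -0.19 and the G2/M median -2.84. Genes that the subtraction took below 0 were set to the floor, so the -2.84 does not give a size. Free RNA was estimated at 17.2% of UMIs in Control and 6.31% in Null endocrine cells. Neuropeptide Y, Npy, stood at 1.74, C2cd4a at 1.88 and Arhgap36 at 1.43, and with clusters weighted alike at 1.16, 1.02 and 0.78. Cells with Mki67 or Top2a were 17.0% of Control and 5.70% of Null endocrine cells after thinning (22 and 34 left out), and 53.9% and 35.9% before. In endocrine progenitor-like cells the progenitor genes had a median of 0.08, with 9 of 16 higher, while S phase and G2/M genes had medians of -0.57 and -0.51, with all 25 and all 30 lower, and the G2/M median ran from -1.16 in barcodes of at least 5000 UMIs to -0.13 under the stricter filter. There Serpina1c stood at 1.75, Tff3 at 1.55, Gast at 2.46, Peg10 at -1.09 and Fam111a at -1.24, and Gast was -1.29 in barcodes of at least 5000 UMIs. In all other kept cells Serpina1c stood at 1.65, so its difference reaches beyond endocrine progenitors. Tff3 stood at 0.21, Gast at 0.04, Peg10 at -0.10 and Fam111a at 0.02 there. Free RNA was estimated at 17.2% and 6.90% of UMIs in endocrine progenitor cells. The endocrine cluster with the most cells in both libraries, led by Gcg, held 468 Control and 341 Null cells, the one led by Ins1 and Ins2, with Npy among its leading genes, held 185 and 196, and the progenitor cluster with the most cells, led by Neurog3, held 403 and 189. An epithelial cluster left unnamed, with Gcg, Xist and the G2/M gene Ube2c among its leading genes, held 326 Control and 15 Null cells that enter neither class. Another unnamed epithelial cluster, led by Onecut2, Nr2f2 and Vcan, held 0 Control and 59 Null cells. It matched the ductal or bipotent progenitor markers best, and what these cells are was not tested.

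**Figure D3:**
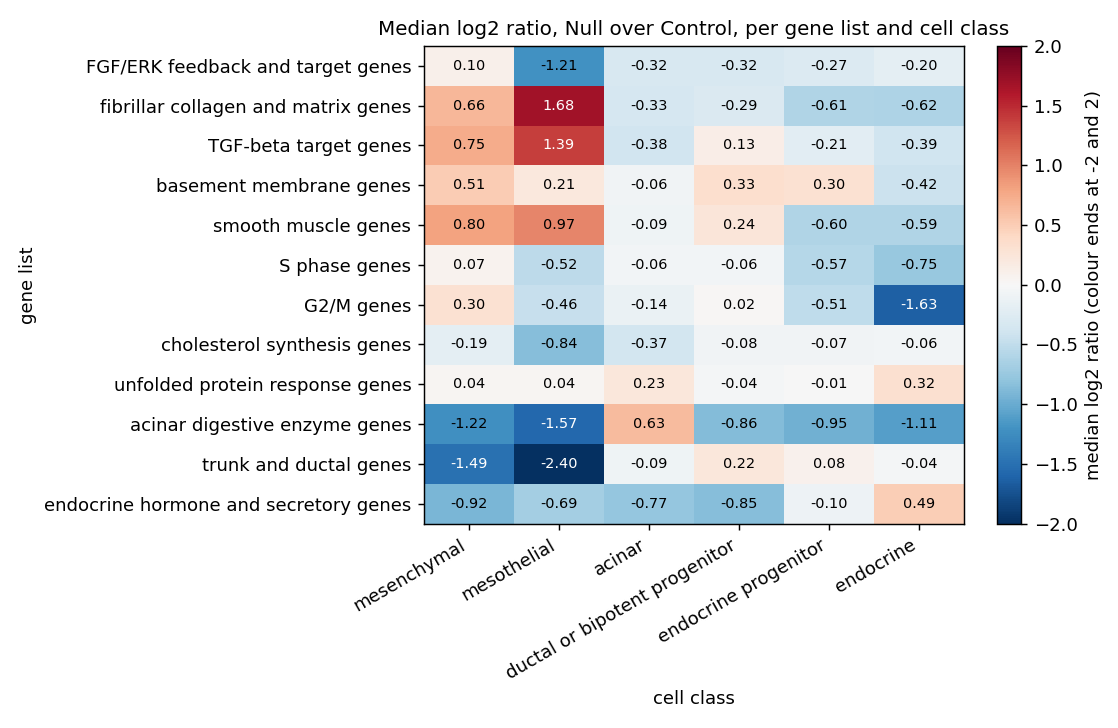
Median log2 ratio of Null over Control for gene lists (vertical axis) in 6 cell classes (horizontal axis), with the value printed in each cell and colour limited at -2 and 2. Matrix genes stand at 0.66 in mesenchymal and 1.68 in mesothelial cells, and FGF/ERK genes at -1.21 in mesothelial cells; the G2/M medians of mesenchymal, mesothelial and acinar cells turn sign with clusters weighted alike.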

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

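Of the tests below, those on the sex of the pooled embryos were chosen before their result was seen; those on free RNA, doublets, neighbouring tissue, the dissociation response and dividing endocrine cells were chosen only after it was seen.

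Several gene lists had medians of opposite sign in different classes, and none of these differences was tested. The gap in log2 median was 1.01 for Wnt and R-spondin ligands between mesothelial and acinar cells, 1.78 for TGF-beta targets, 2.30 for matrix genes between mesothelial and endocrine cells, and 1.93 for G2/M genes and 0.93 for basement membrane genes between mesenchymal and endocrine cells. It was 2.20 for acinar enzymes between acinar and mesothelial cells. Their mesothelial median was 0.50 once free RNA was subtracted, but the subtraction is scaled on these enzymes and removes their total by construction. That gap may largely measure free RNA, but the value of 0.50 cannot show it. The gap was 1.41 for hormone genes between endocrine and mesenchymal cells, where the mesenchymal median of -0.92 turned to 0.37 after the subtraction. Data outside the comparisons also stood out. The unnamed low-UMI cluster held 10837 Control and 310 Null barcodes, and Y-linked Ddx3y stood at 58.1 CPM in the Null and 27.5 CPM in the Control library.

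Tlx1, Nkx2-5, Nkx3-2 and Barx1 were lower in Null mesenchymal cells, with a median log2 ratio of -2.69. These 4 genes were picked because they were low, from a list whose own median was 0.18. Sex of the embryos argues the other way, since Y-called over X-called Control cells gave 0.39 (0.21 to 0.65). Subtraction of free RNA left a median of -2.95, so RNA from other cells in the Control library is not the whole source. With clusters weighted alike the median was -2.47, which leaves open whether the Null dissection held less neighbouring spleen or stomach mesenchyme, because cells can be missing within a cluster as well. Loss of those cells or of their gene expression through the genotype may equally account for it, and with 1 library per group these cannot be told apart.

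FGF/ERK feedback and target genes were lower in Null mesothelial cells. Y-called over X-called Control cells gave a median of 0.0765, which argues against sex. After free RNA was subtracted the median was -1.22, the result set for free RNA not being the source. The subtraction cannot decide this, because whether it removed epithelial RNA from the class is not known. Without barcodes of the second doublet call, trunk and ductal genes stood at -1.34 before it and -1.90 after it. Genes taken below 0 by the subtraction are set to the floor of 3 counts, so -1.90 does not give a size. A stronger dissociation response in the Control library is argued against by the immediate early list, which stood at 0.58 in these cells. Doublets with epithelial cells in the Control library stay open. A second doublet call marked 189 of 1159 scored Control mesothelial cells and 3 of 462 Null ones, and without them the median was -0.72. Trunk and ductal genes still stood at -1.34 there and acinar enzymes at -0.76. Krt19 and Krt7 on the trunk list are also fixed mesothelial markers, so its median does not measure epithelial RNA alone. Once free RNA was subtracted as well, trunk and ductal genes stood at -1.90 and the FGF/ERK median at -0.67. Part of the difference is left, but epithelial RNA may not be fully removed. The differing mesothelial clusters are open too, since the median was -0.72 with clusters weighted alike. A reduced response to FGF signaling in the Null mesothelium may add to these, as a hypothesis found and examined on the same libraries. That hypothesis cannot be told apart from the doublets or from free RNA here. Phosphorylated ERK measured in the mesothelium of sex-matched Control and Null embryos would test it.

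G2/M genes were lower in Null endocrine cells, which may in large part be free RNA. It accounted for 81.9% of G2/M UMIs in Control endocrine cells and 74.7% in Null ones, out of 939 and 395 CPM over all UMIs of the class. What remained in endocrine cells was 170 and 99.8 CPM, still lower in the Null library, and that remainder is open. The per-gene median after subtraction was -2.84. Genes taken below 0 by the subtraction were set to 0 and then to the floor of 3 counts, so that median does not give the size of the difference. Sex is argued against by a Y over X median of 0.17. More dividing endocrine cells in the Control library stay open. Cells with G2/M UMIs as high as in the median acinar cell of both libraries were 1.27% (0.756 to 2.00) of Control and 0.783% (0.315 to 1.61) of Null endocrine cells. With the unnamed clusters that match endocrine cells best, they were 14.8% (13.2 to 16.5) and 2.51% (1.59 to 3.74), a ratio of 0.169. Those clusters held 490 Control and 24 Null cells with median counts of 38244 and 65767 UMIs, and the second doublet call marked 402 of 483 scored Control and 6 of 24 Null cells in them, so many may be doublets. Without the marked barcodes the shares were 3.95% (3.02 to 5.07) and 2.21% (1.35 to 3.39).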

How the results depend on the processing

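The barcode set of at least 5000 UMIs, the removal of barcodes from its doublet call, the named-class denominator, the comparison of cells with Y-linked UMIs and the subtraction of free RNA were chosen only after the results were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because each group is 1 pooled library. The planned free RNA subtraction scaled on haemoglobin was not run, since haemoglobin UMIs were too few. Which list medians are given here in full was decided after the results were seen. Of 60 list medians, 39 kept their sign under every alternative run. Of 823 alternative values of these medians, 39 had the opposite sign, 19 of them for medians whose counting interval excluded 0 and 20 for medians whose interval held 0. The latter 20 come from mesenchymal FGF/ERK genes (0.10, lowest -0.07), FGF ligands in mesenchymal (0.03, lowest -0.37), mesothelial (0.39, lowest -0.26) and acinar cells (0.15, lowest -0.14), mesenchymal hedgehog genes (0.04, lowest -0.13) and ductal G2/M genes (0.02, lowest -0.14). Of the 823 values, 580 stayed within the interval. Of the alternative values of 74 single genes and Fgf9, 350 stayed within the interval, 207 lay outside it and 3 turned sign. Among named genes that moved by more than their interval were mesothelial Vtn (-2.62, and -1.38 as the mean over cells, -1.82 with clusters weighted alike, -1.45 in the set of at least 5000 UMIs and -5.14 with free RNA subtracted), Ppp1r14c (-3.83, and -3.01 as the mean over cells) and endocrine C2cd4a (1.88, and 1.25 after thinning). Depth limits single genes of few UMIs, such as Spry4 in mesothelial cells. Medians that kept their sign but lost much of their size include mesothelial BMP (0.52 to 0.08) and Notch genes (-0.64 to -0.18), S phase genes in mesothelial (-0.52 to -0.23) and endocrine cells (-0.75 to -0.19) and endocrine progenitor G2/M genes (-0.51 to -0.13). Where a value below moved, the cause was not tested unless stated.

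Shares are given as Null over Control. The mesenchymal share of kept cells was 1.02, and 1.18 with 50 principal components, 1.21 at resolution 0.5, 0.903 at resolution 2, 0.629 in the set of at least 5000 UMIs, 0.624 over named cells, 0.707 over every deposited barcode and 0.657 under the stricter filter. The mesothelial share of 1.41 turned to 0.658, 0.867, 0.979 and 0.835 under the last 4 of these in the same order. The epithelial share of 1.83 moved to 1.10, 1.12, 1.10 and 1.26 likewise, and to 1.77 with doublets kept. The low-UMI Control barcodes leave the denominator in the named-class setting by construction. The acinar share of epithelial cells, 1.27, was 1.18 at resolution 0.5, 1.22 at resolution 2, 1.20 in the set of at least 5000 UMIs, 1.22 with doublets kept, 1.22 without barcodes of the second doublet call and 1.20 over every barcode, and the endocrine progenitor share of 0.707 was 0.617 in the set of at least 5000 UMIs. The ductal or bipotent progenitor share of 0.945 was 0.708 with doublets kept, 0.720 at resolution 2, 0.714 with 50 principal components and 0.807 in the set of at least 5000 UMIs. The share of cells with Mki67 or Top2a moved without thinning to 0.741 in endocrine progenitors and 0.667 in endocrine cells, and with thinning to 1000 UMIs to 0.687 in endocrine progenitors, 1.13 in mesenchymal and 0.675 in mesothelial cells.

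Among list medians, scaling moved acinar enzymes in acinar cells to 0.64 (CPM over all genes), 0.65 (TMM) and 0.65 (median of ratios), mesenchymal matrix genes to 0.64 (TMM) and endocrine hormone genes to 0.52 (median of ratios). In the set of at least 5000 UMIs the values were -0.72 for mesothelial FGF/ERK genes, 0.16 and -0.14 for G2/M genes in mesenchymal and mesothelial cells, 0.46 for endocrine hormones, and 0.55 and 1.62 for matrix genes in mesenchymal and mesothelial cells. In that set the mesenchymal and mesothelial classes each hold a cluster with more markers of another class than of its own among its leading genes, so its values for these classes compare a different mix of cells. There mesothelial genes in mesenchymal cells turned to 2.34, FGF receptors in mesothelial cells to 0.0047, Actg2 in mesenchymal cells to -0.68 and Gast in endocrine progenitors to -1.29. Cells with Y-linked UMIs gave 0.42 for mesenchymal G2/M genes, 0.57 for acinar enzymes, 0.42 for endocrine hormones and 0.70 for mesenchymal matrix genes, and turned the spleen and stomach mesenchyme factors to -0.038. Clusters weighted alike gave -0.20 and -0.72 for acinar and mesothelial FGF/ERK genes, -1.19 for endocrine G2/M genes, 0.40 for acinar enzymes, 0.42 for endocrine hormones, and 0.37 and 1.495 for matrix genes in mesenchymal and mesothelial cells. That weighting turned G2/M genes to 0.0104 in acinar, -0.07 in mesenchymal and 0.21 in mesothelial cells, ductal S phase genes to 0.069, mesenchymal Wnt targets to 0.12 and endocrine Gm8251 to 0.23.

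Without barcodes of the second doublet call, mesothelial FGF/ERK genes stood at -0.72, mesothelial G2/M genes at -0.35, mesothelial matrix genes at 1.51 and acinar enzymes in mesothelial cells at -0.76, and other headline medians stayed within their intervals. With doublets kept, mesothelial FGF/ERK genes stood at -0.80, G2/M genes at -1.41 in endocrine, 0.25 in mesenchymal and -0.39 in mesothelial cells, acinar enzymes at 0.65, and matrix genes at 0.64 and 1.52 in mesenchymal and mesothelial cells, while ductal S phase genes turned to 0.026 and endocrine progenitor genes in their class to -0.021. Thinning to 2000 UMIs gave -0.74 for mesothelial FGF/ERK genes, -1.72, 0.17 and -0.59 for G2/M genes in endocrine, mesenchymal and mesothelial cells, 0.55 for endocrine hormones, and 0.80 and 1.52 for matrix genes in mesenchymal and mesothelial cells, and turned mesenchymal S phase genes to -0.027 and mesothelial Wnt and R-spondin ligands to -0.053. Subtracting free RNA gave -2.84 and -0.52 for G2/M genes in endocrine and mesothelial cells, 0.32 for endocrine hormones, and 0.40 and 1.39 for matrix genes in mesenchymal and mesothelial cells. Genes taken below 0 were set to the floor of 3 counts, so the -2.84 does not give the size of the endocrine G2/M difference. The subtraction is scaled on acinar enzymes, so their turn to 0.60 in mesenchymal and 0.50 in mesothelial cells tests nothing. It also turned mesothelial genes in mesothelial cells to -0.063 and endocrine progenitor genes to -0.09. The mean over cells gave -0.21 and -0.70 for acinar and mesothelial FGF/ERK genes, -1.42, 0.13 and -0.55 for G2/M genes in endocrine, mesenchymal and mesothelial cells, and 0.63 and 1.34 for matrix genes in mesenchymal and mesothelial cells, with endocrine progenitor genes in endocrine cells turning to 0.0004. The stricter filter gave -0.80 for mesothelial FGF/ERK genes, -1.46 and -0.31 for G2/M genes in endocrine and mesothelial cells, 0.43 for endocrine hormones, and 0.57 and 1.49 for matrix genes in mesenchymal and mesothelial cells, and turned FGF receptors in mesothelial cells to 0.047 and endocrine progenitor genes in endocrine cells to 0.0028.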

Other observations

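Signaling ligands outside the FGF family also differed in the mesothelial layer. Of 12 measured Wnt and R-spondin ligands, 8 were higher in Null mesothelial cells, with Wnt11 at 3.14, Wnt2 at 2.81 and Wnt4 at 1.86 on the log2 scale, while Wnt7b stood at -2.07 and Wnt5a at -1.42. The median of 0.55 was -0.05 with every cell thinned to 2000 UMIs. Hedgehog pathway genes had a median of 0.41 in this class (0.14 at the lowest of its alternatives), with 8 of 10 higher and the target gene Gli1 at 1.58. In the retinoic acid pathway, Cyp26a1, which degrades retinoic acid, stood at 4.24 and Aldh1a1 at 1.82, while the binding proteins Crabp1 and Crabp2 stood at -3.51 and -1.08.

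Acinar and tip transcription factor genes had a median of 0.09 in acinar cells, with Mycn at -0.61 and Ptf1a at -0.06.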
